A study of Gallus gallus with 58 samples.

How the data were processed

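Whole blood of newly hatched chicks (Gallus gallus) was profiled on an Affymetrix gene array, 1 array per chick and 58 chicks in all. Per the labels' protocols, blood was taken into PAXgene tubes, total RNA was extracted and treated with DNase, and biotin-labelled targets were made with the WT PLUS protocol. The deposited table holds RMA expression values on the log2 scale, per the submitters' processing notes; RMA corrects background, normalizes by quantiles and summarises probes by median polish. Its version and settings are not given in the sources used here. The values were used as deposited. They ran from 1.12 to 14.7, and the array medians lay between 6.64 and 6.78. Signal over background is not known from the table.

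Chicks were grouped by the treatment and time in their labels. The groups were controls at 3 h (10 chicks), CpG at 3 h (10), controls at D3 (8), CpG at D3 (8), controls at D6 (12) and CpG at D6 (10). What the control chicks received is not stated in the labels used here, and neither sex nor hybridisation batch is given. The groups share no chick numbers, so that no chicks were paired.

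The table has 20804 probe sets. The platform table gave exactly 1 gene symbol for 12300 of them, several for 256 and none for 8248. Symbols of 11727 probe sets were checked through their Entrez identifiers against the gene table of assembly GRCg7b, which was used for names and gene neighbours alone. A probe set with several symbols was left unnamed. In total 1644 rows shared all their values with another row, and 2020 rows had identifiers below the first annotated probe set. These rows could not be told to be control probes, so they stayed in the tests, and fits without them were tried. For a gene with several probe sets (651 genes), the probe set with the highest mean over all arrays stood for the gene.

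Tests used limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 58 arrays with lmFit and eBayes (52 residual and 4.17 prior degrees of freedom), 8 contrasts were taken, and p-values (all two-sided) were adjusted by Benjamini-Hochberg over the 20804 probe sets of each contrast, with a threshold of 0.05. The contrasts were CpG against control at each of the 3 times, the 3 changes of that effect between times, and control chicks at D3 against 3 h and at D6 against D3. SE is limma's moderated standard error of a log2 fold change, and a log2 fold change of 1 is a 2-fold difference. Gene lists (24, of pathways, blood cell types and metabolism) were tested with limma's camera at its preset correlation of 0.01 over 11528 genes, adjusted over the 22 lists tested, and again with a correlation estimated for each list and with fry, whose directional p asks only whether a list's genes move one way on balance. The embryonic globin list (2 measured genes) and the W-linked list, a view of the balance of sexes, were not tested. Listed symbols were matched through current symbols, platform symbols and synonyms, so that DEFB4A stands for avian beta-defensin 2, and LECT2, S100A12 and SH2D6 stand on the heterophil and B cell lists through synonyms. The synonym matches of SH2D6, of TSC22D4 on the immediate early list and of RPS4Y1 on the ribosomal list are doubtful.

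Groups, contrasts, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 10 largest rises and falls among called genes with an official symbol, 5 each way for changes of the effect, and up to 4 genes with the smallest p of each list that has a called member or passes its test. It also takes a set of fixed immune genes in each CpG effect. Of these, TLR21, MYD88 and IL10 had no probe set with that symbol alone and are not analysed here.

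The steps were tested on simulated log2 values with the residual spread of each of the 20804 probe sets and 200 changed probe sets in each of the 8 contrasts. Values were drawn independently for each probe set, whereas real genes vary together (estimated correlation 0.74 for the interferon-stimulated list). The rates below hold for independent genes only and do not carry over to calls or lists of correlated genes. Of the 2-fold changes 79.1% to 97.0% were recovered, of the 1.5-fold changes 40.3% to 83.6% and of the 3-fold changes 95.5% to 100%. Between 3.12% and 6.90% of the calls were false when a list of 29 genes was also shifted by 0.5, and camera called that list in 7 of 8 contrasts. It missed the change of the effect from 3 h to D6, and called the list in 8 of 8 contrasts when it was shifted by 1, a shift added after that miss was seen.

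Alternatives were a filter that leaves out the 40% of probe sets with the lowest means, fits of a contrast's own arrays, a trended and robust prior, array weights, repeated quantile normalization, median centring, 1 probe set per gene, the W-linked mean as a covariate, and 6 cell type scores as covariates. A score is the mean z-score of the heterophil, monocyte, thrombocyte, B cell, T cell or erythroid list in an array. Alternatives chosen after seeing the data were merging identical rows (19909 rows left), keeping named probe sets alone, leaving out 4 arrays, leaving out each array of a CpG contrast in turn, the first component of the residuals as a covariate, and repeated normalization or centring for the gene lists. Those 4 arrays had a median correlation with the other arrays of their group more than 3 scaled median deviations below the median of all arrays.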

Results

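Blood transcripts were compared between chicks given CpG-ODN 2007, a short DNA that the labels describe as an agonist of the chicken receptor TLR21, and control chicks. The injection was made on the day of hatch, and blood was taken 3 h (10 CpG, 10 control), 3 days (D3, 8 and 8) or 6 days (D6, 10 and 12) later from different chicks. Each array gave log2 values for 20804 probe sets. The median correlation of an array with the others of its group was between 0.971 and 0.975 over the 6 groups.

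The first question was whether a response could be seen in blood 3 h after the injection. No gene passed the test at this time. IL1B and IL6, which encode inflammatory cytokines, differed by -0.09 ± 0.08 (log2, SE) and -0.05 ± 0.09, and IFNG, which encodes interferon gamma, differed by -0.09 ± 0.10. NOS2, the inducible nitric oxide synthase, differed by 0.00 ± 0.12, NFKBIA, an inhibitor of NF-kB, by -0.16 ± 0.15, and MX1, an antiviral gene induced by interferon, by -0.63 ± 0.49. The chemokine genes IL8L1 and IL8L2 differed by -0.08 ± 0.09 and -0.07 ± 0.12. In the 3 h controls IFNG ranged from 2.84 to 3.68 and IL8L1 from 4.7 to 5.33. These values lie under 6.26, the level below which 40% of probe set means fall. IL6 was also under that level in the CpG chicks at D6 (4.93 to 5.66). Whether IFNG, IL8L1 and IL6 were detected is not known, so that their small differences say little about a response.

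At 3 h limma called 0 of 20804 probe sets, with a smallest adjusted p of 0.168, and 1037 had an unadjusted p under 0.05, where 1040.2 are expected by chance. With array weights 8 probe sets passed, and with the 6 cell type scores as covariates 9. Ribosomal protein genes were slightly higher as a list (median log2 fold change 0.07 over 37 genes, adjusted p = 0.0015) and thrombocyte genes lower (-0.11 over 16 genes, adjusted p = 0.0475), with 0 members called in either, also when adjusted over the list alone. With an estimated correlation the adjusted p = 0.836 for both lists, and fry gave an adjusted p of 0.731 for both. With repeated quantile normalization camera called 0 lists higher and 2 lower, so that the ribosomal call ended.

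At D3 the question was which genes differ 3 days after the injection. Genes for antimicrobial peptides of heterophils, the avian counterpart of neutrophils, rose in the CpG chicks. AvBD7, a beta-defensin (probe set mean 9.73 ± 0.63, SD, n = 8, against 7.38 ± 0.95 in controls, n = 8), rose by 2.35 ± 0.46 (SE, adjusted p = 0.00701), and LECT2, which encodes a secreted leukocyte chemotactic factor, by 2.18 ± 0.33 (adjusted p = 0.000272). DEFB4A rose by 1.73 ± 0.30, AvBD1 by 1.43 ± 0.29 and AvBD4 by 1.00 ± 0.16. In each of these 5 genes all 8 CpG chicks lay above all 8 controls, and AvBD6 rose by 1.38 ± 0.30 with 6 of 8 above. Other heterophil genes on the same list did not pass, among them CSF3R, the receptor of granulocyte colony-stimulating factor, at -0.08 ± 0.22.

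Of the 18 measured heterophil genes 6 rose at D3 and 12 did not pass, and 9 rose when adjusted over the list alone. Their median log2 fold change was 0.37 (camera adjusted p = 5.02e-09, and adjusted p = 0.31 with an estimated correlation), and fry called 2 lists at D3, this and glycolysis. The interferon-stimulated list was higher as a whole, with a median of 0.66 and all 29 genes above 0 (adjusted p = 9.09e-10, and adjusted p = 0.493 with an estimated correlation). Of its members, IRF1, a transcription factor of the interferon response, rose by 1.03 ± 0.23 (7 of 8 chicks above all controls), and 3 rose when adjusted over the list alone. MX1 was at 0.90 ± 0.55 and did not pass (adjusted p = 0.42).

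Cell cycle genes were lower as a list at D3 (median -0.34 over 27 genes, adjusted p = 5.55e-05), with 0 members called, also when adjusted over the list alone, and adjusted p = 0.493 with an estimated correlation. PLK4, a kinase of centriole duplication, is not on that list and fell by 0.87 ± 0.21. Glycolysis genes (median 0.21, adjusted p = 0.00101, and adjusted p = 0.31 with an estimated correlation) included LDHA, the lactate dehydrogenase A chain, which rose by 0.49 ± 0.12, and 6 of 19 rose when adjusted over the list alone. The MHC list (adjusted p = 0.0205, and adjusted p = 0.493 with an estimated correlation) held TAP2, a peptide transporter, which rose by 0.63 ± 0.14, with 2 of 14 genes higher when adjusted over the list alone. The TLR list (median 0.17, adjusted p = 0.000889, and adjusted p = 0.353 with an estimated correlation) had 0 of 20 members called, and 4 rose when adjusted over the list alone. The TLR and glycolysis lists were no longer called with the 6 cell type scores as covariates (adjusted p = 0.945 for both).

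Further genes that rose at D3 were ENPP3 (1.21 ± 0.29), LY86 (1.03 ± 0.24), a partner of a TLR4-like surface receptor on leukocytes, PLOD2, a lysyl hydroxylase of collagen (0.90 ± 0.19), and F13A1, the coagulation factor XIII A chain (0.81 ± 0.19). Genes that fell were SMOC1 (by 1.43 ± 0.34), SLC6A13 (by 0.79 ± 0.16), PSD (by 0.75 ± 0.15), ZNF367 (by 0.56 ± 0.13), GEM (by 0.42 ± 0.10) and UBAP2L (by 0.40 ± 0.09). The mean heterophil score was 0.92 ± 0.59 (SD, n = 8) in the CpG chicks and 0.09 ± 0.38 in the controls, and the erythroid score -0.02 ± 0.27 against 0.14 ± 0.19. CpG chick 14 lowered the erythroid mean, at -0.60 against -0.14 to 0.26 in the other CpG chicks.

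In all, 65 probe sets passed at D3, of which 50 were higher and 15 lower, and 14 differed at least 2-fold. With the 6 cell type scores as covariates 1 probe set passed: of the 65, 0 were still called, their median absolute log2 fold change went from 0.61 to 0.48 and their median SE from 0.13 to 0.16. The 5 defensin genes and LECT2 belong to the list behind the heterophil score. LY86 belongs to that behind the monocyte score and F13A1 to that behind the thrombocyte score. These genes are thus in part adjusted for themselves, so that the loss of their calls does not show a change of the cell mix. The count was 9 in a fit of the D3 arrays alone (9 higher and 0 lower), 144 with array weights (88 and 56) and 123 without 4 arrays that stood apart (77 and 46). It was 30 without CpG chick 14, 40 without 18, 147 without 20, and 42, 42, 101 and 183 (103 higher and 80 lower) without control chicks 85, 87, 88 and 90. Of 16 arrays left out in turn, 11 ended the call of ENPP3, 9 those of LDHA and PLK4, 8 that of SMOC1, 7 those of GEM and ZNF367, 6 that of F13A1, 5 that of LY86 and 1 those of IRF1, TAP2, PLOD2 and UBAP2L. None ended those of the 5 defensin genes, LECT2, PSD and SLC6A13. In the fit of the D3 arrays alone, however, AvBD1, AvBD6, PSD and SLC6A13 were no longer called.

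**Figure D1:**
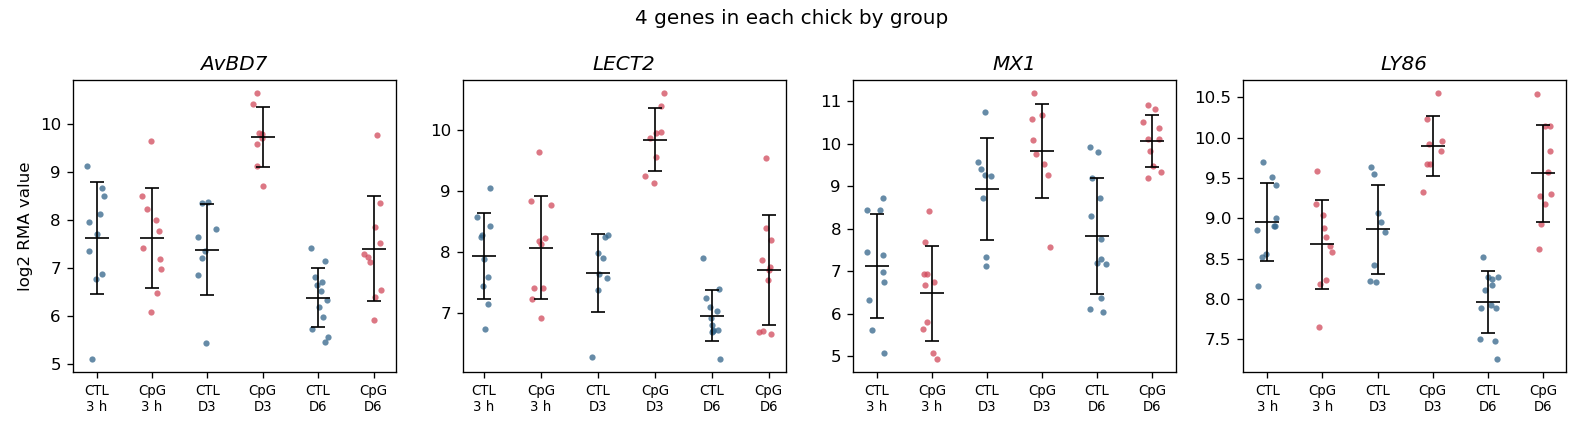
Log2 RMA values (vertical axis) of AvBD7, LECT2, MX1 and LY86 in each of the 58 chicks (points), by group, with the group mean and SD (black bars). At D3 all 8 CpG chicks lie above all 8 controls for AvBD7 and LECT2, and at D6 all 10 CpG chicks lie above all 12 controls for LY86.

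At D6 genes of antiviral defence, of monocytes and of antigen presentation were higher in the CpG chicks. MX1 rose by 2.25 ± 0.47 (SE), from 7.82 ± 1.37 (SD, n = 12) in controls to 10.1 ± 0.60 (n = 10), with 6 of 10 CpG chicks above all controls (adjusted p = 0.00383). DDX60, an interferon-induced helicase, rose by 2.10 ± 0.44 (6 of 10 above, adjusted p = 0.00377). LY86 rose by 1.59 ± 0.21 (adjusted p = 1.54e-06) and FGL2, a fibrinogen-like protein, by 1.36 ± 0.21 (adjusted p = 9.61e-05), both with 10 of 10 CpG chicks above all 12 controls. SPI1, the myeloid transcription factor PU.1, rose by 1.31 ± 0.21 and was above all controls in 9 of 10. In the CpG effects a rise or fall is a difference from controls of the same time, not a change over time. SPI1 and LY86 themselves fell in control chicks from D3 to D6, as given below.

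All 3 of these gene groups moved as lists at D6. Of 29 interferon-stimulated genes 4 rose (MX1, DDX60, IRF1 and ADAR, an RNA editing enzyme), 25 did not pass, and 23 rose when adjusted over the list alone. Their median was 0.72 (adjusted p = 6.21e-17, and adjusted p = 0.106 with an estimated correlation). Of 14 MHC genes 5 rose, among them CTSS, a lysosomal protease (0.73 ± 0.13, 10 of 10 above all controls), TAP2 (0.61 ± 0.12), B2M, the beta-2 microglobulin (0.39 ± 0.08), and BF2, a classical class I gene (0.68 ± 0.18), and 8 rose when adjusted over the list alone (adjusted p = 9.7e-08, and adjusted p = 0.022 with an estimated correlation). Of 13 monocyte genes LY86, SPI1, TREM2 and TLR4 rose, also when adjusted over the list alone (adjusted p = 3.99e-05, and adjusted p = 0.0493 with an estimated correlation).

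TLR pathway genes were also higher at D6. Of 20 measured, 4 rose, among them TLR7, a receptor for single-stranded RNA (0.92 ± 0.17, 10 of 10 above all controls), TLR4, the receptor for bacterial lipopolysaccharide (0.68 ± 0.16), and its partner LY96 (1.06 ± 0.29), and 7 rose when adjusted over the list alone (adjusted p = 2.73e-08, and adjusted p = 0.0285 with an estimated correlation). The TLR list was not called with the 6 cell type scores as covariates, at a median of -0.03 against 0.22 without them (adjusted p = 0.906). IL15 (1.26 ± 0.28) and IL18 (0.64 ± 0.13) rose among 20 cytokine genes (adjusted p = 0.0287, and adjusted p = 0.275 with an estimated correlation); over the list alone 3 rose and 1 fell. SOCS1, a feedback inhibitor of cytokine signalling, rose by 1.07 ± 0.28. IL1B (-0.22 ± 0.08), IL6 (-0.05 ± 0.09), IFNG (0.15 ± 0.10), NOS2 (-0.10 ± 0.11), NFKBIA (0.16 ± 0.14), IL8L1 (0.03 ± 0.08) and IL8L2 (0.13 ± 0.11) did not pass at D6, nor did any of these 7 at D3. IL6 lay between 4.93 and 5.66 in the CpG chicks at D6, a low level at which its detection is not known.

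The heterophil genes called higher than in same-day controls at D6 were others than at D3: ITGB2, a leukocyte integrin (0.86 ± 0.17), NCF4, of the NADPH oxidase (0.60 ± 0.13), CSF3R (0.76 ± 0.19) and S100A12 (1.02 ± 0.26). CSF3R and S100A12 fell in control chicks from D3 to D6, as given below. The mean heterophil score went from 0.09 at D3 to -0.68 at D6 in controls, and from 0.92 to -0.03 in CpG chicks. These differences are thus not shown to be rises over time. AvBD7 (1.03, adjusted p = 0.169) and LECT2 (0.75, adjusted p = 0.173) did not pass at D6, though their change from D3 to D6 did not pass either. Of 18 heterophil genes 8 rose and 1 fell when adjusted over the list alone (list adjusted p = 6.66e-08, and adjusted p = 0.0811 with an estimated correlation). Of 16 thrombocyte genes SELP, GP9 and TBXAS1 rose (0.51 ± 0.12, 0.55 ± 0.14 and 0.51 ± 0.13), and 8 over the list alone (adjusted p = 1.26e-05, and adjusted p = 0.0565 with an estimated correlation). CD44, an adhesion receptor, was the 1 of 21 T cell genes to rise (0.90 ± 0.18; list adjusted p = 0.00541, and adjusted p = 0.275 with an estimated correlation).

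Genes of energy metabolism and division moved too at D6. LDHA (0.55 ± 0.10), HK1, a hexokinase (0.43 ± 0.09), PFKP (0.40 ± 0.09) and PFKFB4 (0.43 ± 0.11) rose among 19 glycolysis genes, 5 when adjusted over the list alone (adjusted p = 7.18e-06, and adjusted p = 0.0382 with an estimated correlation). The glycolysis list was not called with those scores as covariates, at a median of 0.04 against 0.19 without them (adjusted p = 0.906). TPX2, a spindle protein, fell by 0.81 ± 0.17 and CDC45, a replication factor, by 0.55 ± 0.14, and 14 of 27 cell cycle genes fell when adjusted over the list alone (median -0.44, adjusted p = 1.17e-10, and adjusted p = 0.0811 with an estimated correlation). BPGM, which makes 2,3-bisphosphoglycerate in red cells, fell by 0.81 ± 0.14, the 1 of 17 erythroid genes to change (list adjusted p = 0.0267, and adjusted p = 0.196 with an estimated correlation). Oxidative phosphorylation genes were lower as a list (median -0.14, 0 of 19 called, adjusted p = 0.0259, and adjusted p = 0.444 with an estimated correlation). Camera called 3 lists lower at D6, but 1 without the 4 arrays that stood apart and 2 with repeated quantile normalization. ASS1 and ASL, 2 enzymes of arginine synthesis, rose by 0.94 ± 0.16 and 0.47 ± 0.12, ACOD1, the itaconate-forming enzyme, by 1.19 ± 0.29 (10 of 10 above all controls), and ODC, ornithine decarboxylase, fell by 0.49 ± 0.14.

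The list of these arginine, tryptophan and polyamine genes did not pass at D6, and neither did those of chemokines, NF-kB feedback, acute phase proteins, B cells, NK cells, fatty acid oxidation, cholesterol synthesis, immediate early genes and ribosomal proteins (adjusted p between 0.057 and 0.871). Within them CD7 rose by 0.74 ± 0.16, SH2D6, whose match to the B cell list through a synonym is doubtful, by 0.66 ± 0.14, and LSS, an enzyme of cholesterol synthesis, fell by 0.34 ± 0.09. The largest other rises were AVD, avidin (1.93 ± 0.36), XK (1.89 ± 0.29), ANXA2 and ANXA1, annexins (1.78 ± 0.26 and 1.43 ± 0.30), ACKR4, a chemokine scavenger (1.64 ± 0.32), and MGST1 (1.37 ± 0.24). The largest falls were SIK1 (by 1.43 ± 0.31), SMOC1 (by 1.09 ± 0.29), ARID5B (by 1.00 ± 0.20), ACSS1A (by 1.00 ± 0.28), PLS1 (by 0.97 ± 0.28) and NR4A3 (by 0.94 ± 0.24). At D6 the mean heterophil, monocyte and thrombocyte scores were -0.03, 0.22 and -0.02 in CpG chicks and -0.68, -0.36 and -0.55 in controls, and the erythroid score was 0.09 against 0.35. CpG chick 31 lowered the erythroid mean, at -0.78 against 0.01 to 0.45 in the other CpG chicks.

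At D6 440 probe sets passed, 317 higher and 123 lower, and 39 differed at least 2-fold. With the 6 cell type scores as covariates 9 passed, all 9 among the 440 (the median absolute log2 fold change of the 440 went from 0.55 to 0.30, and their median SE from 0.13 to 0.14), and among genes named here XK, ACKR4, LY86 and DDX60 were still called while TLR4 went to -0.0225. TLR4 and LY86 belong to the list behind the monocyte score, so that they are in part adjusted for themselves. The count was 682 with array weights and 272 without CpG chick 28. Without CpG chick 31 the calls of SOCS1 (0.83), LY96 (0.84), S100A12 (0.84), GP9 (0.49), SMOC1 (-0.86), ACSS1A (-0.97), PLS1 (-0.79), CDC45 (-0.45) and ODC (-0.33) ended, with adjusted p between 0.0582 and 0.124. Of 22 arrays left out in turn, 16 ended the calls of ACSS1A and PLS1, 15 that of ODC, 13 that of ADAR, 5 that of LY96, 4 those of BF2 and GP9, 3 those of PFKFB4 and SMOC1, 2 those of CDC45, S100A12 and SOCS1 and 1 those of ASL and CSF3R. CpG chick 28 ended the most, among them those of ADAR, BF2, CSF3R and PFKFB4.

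**Figure D2:**
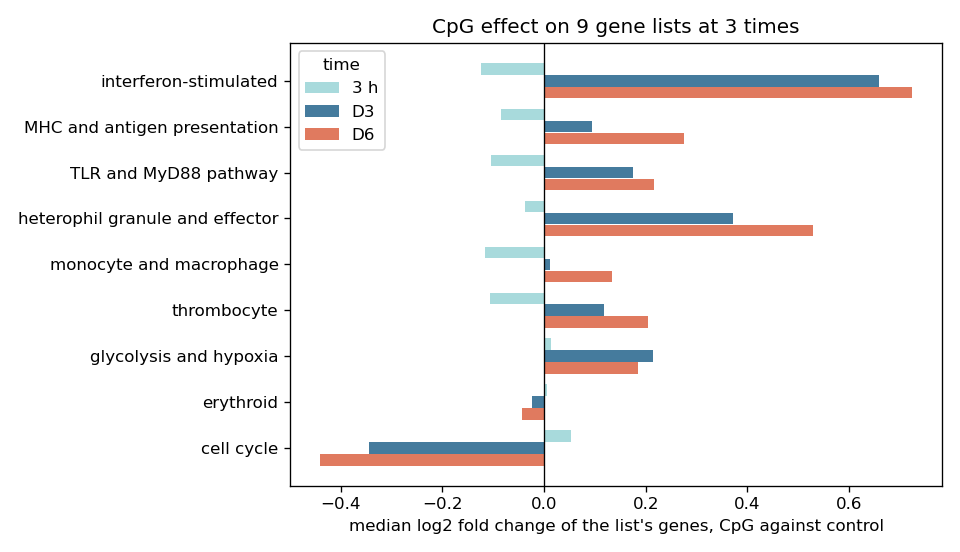
Median log2 fold change of CpG against control chicks (horizontal axis) for 9 gene lists, with 1 bar per time. The interferon-stimulated list reaches 0.66 at D3 and 0.72 at D6, and the cell cycle list -0.34 and -0.44.

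Calls at D3 and D6 were compared with each other, which share no chicks. Of the 50 probe sets higher at D3, 22 were also higher at D6, against 0.762 expected of independent lists, and 49 had the same sign. Of the 15 lower at D3, 3 were also lower at D6 (0.0887 expected) and all 15 had the same sign. LY86, IRF1, TAP2 and LDHA were higher and SMOC1 lower at both times. Across probe sets, which are not independent, the fold changes at D3 and D6 correlated with r = 0.41, those at 3 h and D3 with 0.18 and those at 3 h and D6 with -0.05. The number shared in direction, 25 in all, was 56 with array weights.

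Whether the CpG effect itself differed between times was tested directly. From 3 h to D3 it rose for FGL2 by 1.75 ± 0.33 (SE) and for AvBD4 by 1.10 ± 0.21 (adjusted p = 0.0216 for both), the 2 probe sets that passed. From 3 h to D6 it rose for MX1 (2.88 ± 0.68), FGL2 (2.28 ± 0.30), FN1, fibronectin (2.03 ± 0.39), LY86 (1.87 ± 0.30), XK (1.86 ± 0.42), CSF3R (1.52 ± 0.28) and SPI1 (1.38 ± 0.31). It fell for BPGM (by 0.95 ± 0.21), RTN4IP1 (by 0.76 ± 0.20), YBX1 (by 0.75 ± 0.16), SIAH2 (by 0.60 ± 0.15) and ERCC6L (by 0.57 ± 0.14). In total 124 probe sets passed from 3 h to D6, 115 of them higher. Part of these changes lies in values at 3 h that did not pass there: the effect at 3 h was -0.93 for FGL2, -0.83 for FN1, -0.76 for CSF3R, -0.63 for MX1, -0.28 for LY86, 0.41 for RTN4IP1 and 0.37 for YBX1. FGL2 was at 0.82 at D3 and did not pass (adjusted p = 0.103), and RTN4IP1 and YBX1 did not pass at D6.

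Between D3 and D6 limma called 0 changes of the CpG effect, with 1201 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.0748, and camera and fry called 0 lists. From 3 h to D3 camera called 9 lists, 7 higher and 2 lower, led by the interferon-stimulated (median 0.87, adjusted p = 3.67e-13) and heterophil lists (0.64, adjusted p = 2.59e-12), and 0 with an estimated correlation (adjusted p = 0.221 and 0.104). From 3 h to D6 it called 11, 9 higher and 2 lower, and 4 held with an estimated correlation: TLR pathway (adjusted p = 0.0196), MHC (0.0176), monocyte (0.0196) and thrombocyte (0.0241). With the 6 cell type scores as covariates 0 and 2 probe sets passed for the changes to D3 and to D6, with array weights 5 and 258, and from 3 h to D3 0 passed in a fit of those arrays alone or without the 4 arrays.

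Control chicks were compared between times to describe the background against which the CpG effects were measured. Age, time after whatever the controls received and any batch cannot be told apart in this comparison. From 3 h to D3 genes of dividing cells rose: of 27 cell cycle genes 21 rose and 1 fell, also when adjusted over the list alone (median 1.11, adjusted p = 7.97e-16, and adjusted p = 0.133 with an estimated correlation). E2F1, a transcription factor of the S phase, rose by 2.33 ± 0.23, TPX2 by 1.80 ± 0.18, PLK1, a mitotic kinase, by 1.37 ± 0.18 and, outside the list, NUSAP1 by 2.16 ± 0.27, each with all 8 D3 chicks above all 10 at 3 h. Red cell genes moved both ways: SLC25A37, a mitochondrial iron importer, rose by 0.87 ± 0.12 and EPB42 and SLC4A1, of the red cell membrane, by 0.80 ± 0.13 and 0.49 ± 0.06, and HBE, an embryonic globin, fell by 1.98 ± 0.36. Of 17 erythroid genes 8 rose and 5 fell, 9 and 5 over the list alone (list adjusted p = 0.0622), and of the 2 embryonic globin genes, a list not tested, 1 fell.

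Thrombocyte genes moved the other way in the controls at D3: 9 of 16 fell, among them GP9 (by 1.11 ± 0.16) and FLI1 (by 0.96 ± 0.16), and TUBB1 rose by 1.39 ± 0.17 (adjusted p = 0.00302, and adjusted p = 0.394 with an estimated correlation). Of 21 T cell genes 11 rose and 2 fell, with BCL11B at 0.67 ± 0.14 and CD4 at 0.62 ± 0.15 (adjusted p = 0.0034, and adjusted p = 0.432 with an estimated correlation); over the list alone 12 rose. Of 18 immediate early genes 12 rose and 1 fell, with FOS at 1.23 ± 0.23 and EGR1 at 0.72 ± 0.15 (adjusted p = 0.000286, and adjusted p = 0.394 with an estimated correlation). SMOC1 (2.72 ± 0.32), HPGDS, a prostaglandin D synthase (2.58 ± 0.35), ABCC4 (2.45 ± 0.28), PLCB2 (2.42 ± 0.26) and DDX60 (2.40 ± 0.48) had the largest rises, and OSBPL6 fell by 2.00 ± 0.33, HACD4 fell by 1.82 ± 0.33 and EXOC3L fell by 1.79 ± 0.24. Of 20804 probe sets 5158 passed, 2453 higher and 2705 lower. With the cell type scores 1438 passed, CD4, itself in the T cell score, went to -0.14, and 35.7% of the calls were higher against 47.6%; with 1 probe set per gene 3410 passed.

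From D3 to D6 genes of heterophils, division and glycolysis fell in control chicks. Of 18 heterophil genes 9 fell, among them S100A12 (by 1.24 ± 0.28), CTSG, cathepsin G (by 1.04 ± 0.18) and CSF3R (by 1.01 ± 0.20), and 13 fell and 1 rose over the list alone (adjusted p = 2.89e-05, and adjusted p = 0.485 with an estimated correlation). Of 27 cell cycle genes 9 fell, with CCNB1, a cyclin, by 1.07 ± 0.18 and UHRF1 by 0.98 ± 0.13, and 20 fell over the list alone (adjusted p = 3.96e-08, and adjusted p = 0.485 with an estimated correlation). Of 19 glycolysis genes 12 fell, with GAPDH by 0.63 ± 0.15 and SLC16A3, a lactate transporter, by 0.58 ± 0.12, and 14 fell and 1 rose over the list alone (adjusted p = 2.89e-05, and adjusted p = 0.146 with an estimated correlation). Ribosomal protein genes (7 of 37 fell, with RPL23 by 0.35 ± 0.09, adjusted p = 6.49e-06), TLR genes (5 of 20 fell and 1 rose, with TLR4 by 0.61 ± 0.17, adjusted p = 0.0208) and immediate early genes (2 of 18 fell, with JUN by 0.62 ± 0.15, adjusted p = 0.0111) were lower too. With an estimated correlation the adjusted p = 0.485 for each of these last 3 lists.

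SLC20A1, a phosphate transporter (by 1.85 ± 0.25), DDX60 (by 1.55 ± 0.47), ANXA1 (by 1.34 ± 0.32) and MGST1 (by 1.31 ± 0.26) had large falls in control chicks from D3 to D6. ARID5B rose by 1.39 ± 0.21, RASSF6 by 1.24 ± 0.18 and HEMGN, an erythroid nuclear protein, by 1.00 ± 0.17. SPI1 and LY86 fell by 1.11 ± 0.23 and 0.90 ± 0.22, and the B cell genes CD79B and CXCR5 rose by 0.36 ± 0.08 and 0.38 ± 0.09. In all 3060 probe sets passed, 1407 higher and 1653 lower, and 57 differed at least 2-fold, of which 47 were lower. With the cell type scores 542 passed and TLR4, itself in the monocyte score, went to 0.15. More probe sets were higher than lower with repeated quantile normalization (1677 and 1554), with array weights (2000 and 1946) and without the 4 arrays (2291 and 2130).

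The balance of the sexes, which the labels do not give, was viewed through HINTW, a gene of the female-specific W chromosome. Its log2 value was above 10 in 4 of 10 control and 3 of 10 CpG chicks at 3 h, 4 of 8 and 5 of 8 at D3, and 6 of 12 and 5 of 10 at D6. The 2 measured W-linked genes, which were not tested as a list, had a median log2 fold change of CpG against control of -0.29 at 3 h, 0.27 at D3 and -0.17 at D6, and 0 of the 2 passed at any time.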

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

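The comparison with splits was chosen before its results were seen, except that of top-ranked probe sets. The values tested for single chicks are those of genes named in the text, some of which were chosen after their values were seen, and of array-level measures. An array was singled out where the gap between the highest or lowest chick and the nearest other, divided by the range of its group, exceeded Dixon's 95% critical value. Groups of 8 or 10 chicks could be tested, and the 12 D6 controls were not. Chance singles out about 1 in 20 groups, and 36 of 323 values tested were singled out, 12 of them in CpG chick 31 at D6.

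CpG chick 31 at D6 had the lowest median correlation with its group (0.942, others 0.968 to 0.975; gap ratio 0.788) and a low erythroid score (-0.78, gap ratio 0.641). Its values were high for SOCS1 (gap ratio 0.675), LY96 (0.647), IL6 (0.551) and SH2D6 (0.491). They were low for ODC (0.757), CDC45 (0.666), B2M (0.614), NOS2 (0.581), SMOC1 (0.506) and BF2 (0.487).

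At D3, CpG chick 20 stood apart in median correlation (0.959, gap ratio 0.615), thrombocyte score (0.527), F13A1 (0.567) and TAP2 (0.543), the last 3 on the high side, and CpG chicks 14 and 18 were low in erythroid score (0.534) and UBAP2L (0.604). Control chick 86 stood apart in median correlation (0.947, gap ratio 0.675) and was high in B cell score (0.551), RPL19 (0.556) and RPL23 (0.706). Control chick 90 was low in LECT2 (0.545), E2F1 (0.541), GFI1B (0.616) and CTSG (0.672), and control chick 88 was high in MMRN2 (0.643) and CIAO1 (0.597). At 3 h, control chick 74 stood apart in median correlation (0.946, gap ratio 0.732) and was high in IL8L1 (0.525) and IFNG (0.598). Control chick 75 was high in DDX60 (0.605), control chick 81 low in NUSAP1 (0.523), and CpG chick 2 high in IL8L1 (0.528). CpG chick 10 was low in JAKMIP1 (0.531) and C4H4ORF50 (0.486).

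The CpG effect differed between times by the test of the difference itself. From 3 h to D3 it differed for 2 probe sets (FGL2, 1.75 on the log2 scale, and AvBD4, 1.10) and 9 gene lists, and from 3 h to D6 for 124 probe sets and 11 gene lists. With an estimated correlation 0 of the 9 lists and 4 of the 11 held, and the 2 probe sets dropped to 0 without the 4 arrays or in a fit of the compared arrays alone. Among the 124 were MX1 (2.88), FGL2 (2.28), FN1 (2.03), LY86 (1.87), XK (1.86), IL15 (1.55), CSF3R (1.52), SPI1 (1.38), TLR7 (1.27), ITGB2 (1.20) and TREM2 (1.01) on the higher side, and BPGM (-0.95), RTN4IP1 (-0.76), YBX1 (-0.75), SIAH2 (-0.60) and ERCC6L (-0.57) on the lower side.

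Each count was set against 100 splits of the same arrays into groups of the same sizes, the real split included. The splits argue against chance for the 440 probe sets at D6 (1 split as large, highest other 22). They do so too for the 124 of the change from 3 h to D6 (1 split, highest other 3). The same holds for the 5158 and 3060 of the control comparisons (1 split each, highest others 2516 and 902). A share of 1 in 100 is the smallest that these splits can give, and it was not adjusted for the number of counts compared. The labels give no batch, and splits cannot tell a batch that coincides with the groups from treatment or time. For the 12 gene lists at D6 the evidence against chance was weak (3 splits, the real one included, highest other 12). Other splits reached the same count, and the counts compared were not adjusted for their number, so that chance was not excluded there. For the 25 probe sets shared by D3 and D6 the comparison of calls says little (1 split, highest other 0), since most splits call 0 probe sets. When each split gave as many top-ranked probe sets per direction as were called, 25 were shared by the real split and at most 10 by another (1 split as large). Each split regrouped the chicks of both D3 and D6. That argues against chance at both times at once. It cannot exclude a chance difference at D3 beside a real one at D6.

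Chance could not be excluded for the 65 probe sets at D3, since 9 of 100 splits gave as many, nor for the 2 of the change from 3 h to D3 (5 splits, highest other 6). One other split of the D3 chicks gave 1205, many times the real count. Whether a structure among those chicks that the labels do not name lies behind it was not tested. The counts of 0 probe sets at 3 h and from D3 to D6 and of 0 lists from D3 to D6 are reached by all 100 splits whatever the data, so that the splits test nothing there (highest others 15, 7 and 14). Chance was not excluded either for the 2 gene lists at 3 h (71 splits, highest other 9), the 6 at D3 (42, highest other 12), the 9 from 3 h to D3 (5, highest other 12), the 11 from 3 h to D6 (7, highest other 14), and the 4 and 6 of the control comparisons (66 and 27, highest others 11 and 9).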

How the results depend on the processing

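Alternatives chosen after seeing the data were merged identical rows, named probe sets alone, leaving out 4 arrays or 1 array, the first residual component (15.7% of the residual variance) and the rescaled gene lists. The planned fit with 1 surrogate variable was not run, and that component took its place. No paired analysis was possible because the groups share no chick numbers. Signal over background is not known here, so that low values are limited by the array's floor to an unknown degree. Of 2858 values of named genes under alternatives, 2643 kept their direction and side of the threshold, 202 were no longer called, 10 were newly called and 3 reversed, all 3 with the cell type scores. Most counts below moved by over 1.5 times, and the causes were not tested.

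With the 6 cell type scores as covariates, the counts were 9 at 3 h, 1 at D3, 9 at D6, 0 for the change from 3 h to D3, 2 for that to D6, and 1438 and 542 in the controls from 3 h to D3 and from D3 to D6. The 6 lists behind the scores were left out of the list tests, which leaves 16. Lists called were 3 at D3, 3 at D6, 4 and 5 for the changes to D3 and D6, and 3 in the controls from D3 to D6. Of the earlier calls among these 16, 3 of 5 held at D3, 3 of 7 at D6, 4 of 6 and 3 of 7 for the changes, and 3 of 5 in the controls. TLR4 at D6 (-0.0225), CD4 in the controls at D3 (-0.14) and TLR4 in the controls at D6 (0.15) reversed. So did the lists TLR at D3 (adjusted p = 0.945), TLR and glycolysis from 3 h to D3 (0.951 and 0.621), oxidative phosphorylation at D6 (0.906), cytokines, glycolysis and oxidative phosphorylation from 3 h to D6 (0.974, 0.746 and 0.573) and TLR in the controls at D6 (0.259), none of them past the threshold. Over the alternatives of these 8 results the adjusted p ranged from 4.41e-06 to 0.974. The scores were measured after the injection and hold genes that it changed, and TLR4 and CD4 are among their members.

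Array weights gave 8, 144 and 682 probe sets at 3 h, D3 and D6, 5, 258 and 1 for the changes to D3, to D6 and from D3 to D6, and 56 shared by D3 and D6. Fits of a contrast's own arrays gave 9 at D3 and 0 for the change to D3. Quantile normalization again gave 1 at 3 h, and 1 probe set per gene gave 3410 in the controls at D3. The change from D3 to D6 gave 1 under the filter of low probe sets, 1 probe set per gene, named probe sets and without the 4 arrays. Without those 4, D3 gave 123 and the change to D3 gave 0.

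With an estimated correlation the lists called were 0, 0 and 4 at 3 h, D3 and D6, 0 and 4 for the changes to D3 and D6, and 0 and 0 in the controls. With fry they were 0 at 3 h, 2 at D3, 1 for the change to D3 and 8 and 11 in the controls. At 3 h there were 7 lists under the filter, 5 without the 4 arrays and 4 with centring, the filter and repeated quantile normalization each gave 1 from D3 to D6, and the controls at D3 had 7 without the 4 arrays.

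Leaving out 1 array gave 0 to 5 probe sets at 3 h (5 without CpG chick 2), 30 to 183 at D3 and 272 to 503 at D6. At D3 the count moved by over 1.5 times without CpG chicks 14 (30), 18 (40) and 20 (147) and control chicks 85 (42), 87 (42), 88 (101) and 90 (183), and at D6 without CpG chick 28 (272). With median centring, the W-linked mean, the trended prior, merged rows and the residual component, the counts at D3 were 76, 68, 78, 66 and 77 and at D6 463, 466, 456, 462 and 487.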

Other observations

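All genes of the next 2 paragraphs were chosen after their values were seen, and the tests against other heterophil genes and against red cells were chosen after the results they weigh were seen. At D6 several genes outside the fixed lists were also called, among them LBP and genes known from leukocytes. LBP, which binds bacterial lipopolysaccharide (1.10 ± 0.19, log2 and SE, adjusted p = 0.000393), ALOX5AP, a helper of leukotriene synthesis (1.07 ± 0.18, adjusted p = 0.000387), LCP1, a leukocyte actin-bundling protein (0.95 ± 0.16, adjusted p = 0.000364) and LY75, an endocytic receptor of dendritic cells (0.71 ± 0.09, adjusted p = 8.33e-07) rose by limma, each with all 10 CpG chicks above all 12 controls. Mean values of the CpG chicks at D6 were below those of the 3 h controls for LBP (8.64 against 9.25) and ALOX5AP (8.23 against 8.31). They were above them for LCP1 (8.43 against 8.03) and LY75 (10.6 against 10.2). LTA4H, which makes leukotriene B4, rose by 0.54 ± 0.12, and PTPRC, the common leukocyte antigen CD45, by 0.59 ± 0.11. CTSC, a protease that activates granule enzymes, and LY75 also rose at D3 (0.90 ± 0.21 and 0.55 ± 0.10), where leaving out 1 array ended the call of CTSC for 6 of 16 arrays and that of LY75 for 0. With the 6 cell type scores as covariates LY75 was still called at D6 (0.65 ± 0.10, adjusted p = 0.000466), while LBP, ALOX5AP, LCP1, LTA4H, PTPRC and CTSC no longer were.

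At 3 h, where limma called 0 probe sets without covariates, the fit with the 6 cell type scores called 9. SOCS3, a feedback inhibitor of cytokine signalling (0.94 ± 0.18, adjusted p = 0.0159), IL1R2, a decoy receptor of interleukin 1 (1.45 ± 0.27, adjusted p = 0.0159), and MLKL, an effector of necroptosis (0.77 ± 0.13, adjusted p = 0.00292), were higher, and FGL2 (-0.73 ± 0.14) and CSF3R (-0.62 ± 0.12), itself a member of the list behind the heterophil score, lower. Without covariates SOCS3 was at 0.74 ± 0.17 (adjusted p = 0.168) and IL1R2 at 1.11 ± 0.29 (adjusted p = 0.343). JAKMIP1 and C4H4ORF50, which lie close to each other in the gene table, differed most at 3 h without passing (2.13 ± 0.44 and 2.09 ± 0.45, adjusted p = 0.168 for both). For both, 7 of 10 controls lay below the lowest CpG chick, and the difference was -0.04 and -0.06 at D6.

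The granule genes of heterophils (AvBD1, AvBD4, AvBD6, AvBD7, DEFB4A and LECT2) were higher at D3 with a median of 1.58 and a lowest value of 1.00. A larger share of heterophils in the blood stays open: the 12 others on the list had a median of 0.107, but they are the members not called, so that their low median decides nothing. No single array carried the difference, since the lowest median with 1 array left out was 1.42. More immature myeloid cells were to be excluded if the median of 7 early myeloid genes plus its SD stayed under 0.39, a bound set from the granule median, as it did (median -0.0558, SD 0.36), but that bound assumed how strongly such cells express them, which no value here gives. The 3 of them with means above 6.26 had a median of 0.25 with an SD of 0.49, so that this stays open. An effect of CpG-ODN within cells was not tested, and chance was not excluded for the count at D3.

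The interferon-stimulated list was higher at D6 with a median of 0.72. With the 6 cell type scores as covariates the median was 0.77, which argues against the measured mix of blood cells as the whole cause. The list passed there with camera at the preset correlation (adjusted p = 5.4e-19), and an estimated correlation was not tried with the scores. Over the alternatives the adjusted p ranged from 5.4e-19 to 0.106, the value with an estimated correlation, where the call was lost. With the scores DDX60 was still called, but MX1, IRF1 and ADAR no longer were. The scores hold genes that differed after the injection and cover no NK cells, so that other changes of the mix stay open. A single array is argued against by a median of at least 0.61 with any 1 array left out. Among explanations that stay open, untested here, are the injection itself and exposure of some chicks to a virus, which the labels do not describe. That CpG-ODN raised interferon-stimulated genes 6 days after the injection remains a hypothesis, which no test here decides.

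The cell cycle list was lower at D6 with a median of -0.44. A smaller share of red cells would lower erythroid genes alike, but the erythroid median lay 0.40 above that of the cell cycle list, with an SD of 0.15 when members were permuted. That SD is over genes, which vary together, and not over chicks. The erythroid list was itself lower at D6 (median -0.04, camera adjusted p = 0.0267), so that a part played by fewer red cells stays open. With the 6 scores as covariates the median was -0.32, and the list passed with camera at the preset correlation (adjusted p = 1.83e-09). An estimated correlation was not tried with the scores. Over the alternatives the adjusted p ranged from 1.8e-11 to 0.0811, the value with an estimated correlation, where the call was lost. The median with the scores argues against the measured mix as the whole cause, only as far as the scores capture that mix. With 1 array left out the median nearest to 0 was -0.33. A smaller share of dividing precursors among red cells, which erythroid genes as a whole would not show, could account for the lower list and was not tested.

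Whether these 3 groups of genes varied together was asked over the 58 chicks with group means removed, in 3 relations. Granule and cell cycle scores had r = 0.31 (permutation p = 0.00339, adjusted p = 0.0102) and rho = 0.30 (permutation p = 0.0187, adjusted p = 0.0561), and r = 0.23 without the 2 chicks farthest from the median granule score. Interferon and granule scores had r = -0.08 (permutation p = 0.614) and rho = 0.08 (p = 0.586), and r = 0.10 without 2 chicks. Interferon and cell cycle scores had r = -0.12 (permutation p = 0.295, adjusted p = 0.443) and rho = -0.07 (p = 0.608), and r = 0.00 without 2 chicks.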
